A study of Arabidopsis with 8 samples.

How the data were processed

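The series holds 8 RNA libraries of Arabidopsis thaliana seedlings 5 days old: 2 from Col-0 root, 2 from root of the saur41/40/71/72 quadruple mutant, 2 from Col-0 shoot and 2 from shoot of the mutant. Per the labels, the parts of the seedlings were ground in liquid nitrogen, total RNA was extracted with TRIzol, and a company made the libraries and sequenced them on an Illumina HiSeq. The build is TAIR10 according to the processing notes of the submitters. The aligner, the program that computed the FPKM values, the library type and the number of reads are not given in the sources used here.

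The authors deposited 1 table per library with FPKM values per gene, a gene name and a locus, and each table lists only genes with an FPKM above 0. A gene that is absent from a table was taken as 0 for that library and is called not listed. In all, 25397 genes were listed at least once and 19513 in every library. Of the locus identifiers 25141 were matched in the RefSeq gene table of assembly TAIR10.1, used for symbols and biotypes only, and 256 were not. Coordinates are those of the deposited tables, with 1 added to the start. The tables give overlapping genes 1 merged locus, and 3124 of the tested genes (15.6%) share theirs with another gene. Read counts were not used here, so count models such as edgeR and DESeq2 were not run, and the depth could only be compared within a tissue. For that, the most frequent ratio of the FPKM values of low genes between 2 libraries of a tissue was read as the ratio of what 1 fragment is worth in each. By this measure the depth relative to Col-0 replicate 1 of the same tissue was 0.874, 1.08 and 1.05 for Col-0 root replicate 2 and mutant root replicates 1 and 2, and 0.889, 1.18 and 1.22 for the same shoot libraries. The libraries listed 22774, 22684, 22775 and 22858 genes in root and 21355, 21862, 22360 and 22477 genes in shoot (Col-0 first). The 10 highest genes took 3.53%, 3.94%, 3.62% and 3.48% of all FPKM in root and 17.6%, 16.2%, 13.6% and 12.9% in shoot. Organelle genes took between 0.053% and 3.34% of FPKM.

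The comparisons, tests, filters, gene lists and the first set of alternatives were fixed before the data were examined. Genes with a mean FPKM of at least 1 over the 4 libraries of root or over the 4 libraries of shoot were tested (19985 genes). Log2 of FPKM plus 1 was fitted with limma 3.58.1 in R 4.3.3 as 1 model with 4 groups (genotype by tissue) and 4 residual degrees of freedom, with empirical Bayes moderation that followed the mean trend and was robust. No further scaling was applied. The contrasts were mutant minus Col-0 in root, the same in shoot, their difference (interaction) and root minus shoot in Col-0. P-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, with a threshold of 0.05. Overlap between tissues was tested per direction with a 1-sided Fisher exact test.

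Gene lists, 32 in all, were written from general knowledge by locus: 26 of processes and gene families, which include the mutated genes, and 6 of tissue and cell type markers. Each list with at least 5 tested members (30 lists) was tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and the members were also adjusted over the list alone. The lists of seed storage and oil body genes (4 tested members) and of the mutated genes (3 tested members) were too small and were not tested. The lists of other SAUR genes (76 loci) and of calmodulins (26 loci) were completed with the reference genes whose symbol or synonym is SAUR or CML and a number.

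Genes are named by a rule. It takes the 4 mutated genes, and in each tissue the 10 largest increases and 10 largest decreases among genes with an adjusted p under 0.05, a mean of at least 5 FPKM in that tissue and both mutant values beyond both Col-0 values. It adds the 5 largest changes each way among genes that passed in both tissues, the 5 largest each way for the interaction, and for each list up to 4 members that passed or, where none did, up to 2 with the largest change. Further members of the jasmonate and abscisic acid lists, the genes that passed after rescaling, the neighbours of PI4KG3 and HEI10, AT2G01422 in root, the genes of the tissue comparison and MAF5 were chosen after their values were seen.

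The alternatives fixed beforehand were a pseudocount of 0.1 or 0.5, no filter or a filter of 5 FPKM, median-ratio rescaling over all libraries, quantile normalization within a tissue, each tissue fitted alone, the replicate number as a block, moderation without trend, camera with an estimated correlation, the test fry, a change of at least 2-fold, a threshold of 0.1 or a mean of 5 FPKM in both tissues for the overlap, and each library left out in turn. Added after the data were seen were median-ratio rescaling within a tissue, removal of a gene length trend within a tissue, each of these without Col-0 shoot replicate 1, and leaving out 4 genes not listed in 1 replicate while at 5 FPKM or more in the other (LHCB1.3, PSBZ, AT1G26921 and AT3G41768, which stayed in the analysis reported). From the shares of FPKM taken by a list, however, these 4 genes were left out in the list sum, though not in the total. The gene length trend of each library was a lowess curve (span 0.3) of its deviation from the mean of the tissue against the log2 of the gene span, that is the end minus the start of the locus. It was fitted on genes listed in all libraries of the tissue at a mean of 5 FPKM or more and with a locus of their own. For genes in a merged locus the span is too long, so the removal is approximate for them.

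The steps were tested on simulated data with the means of these libraries. Noise was drawn independently for each gene and library, with 1 spread per gene for all 8 libraries. In the data the Col-0 shoots differed more than the other pairs, and genes of a list varied together. The simulation therefore does not give the error rates for these data. Of 100 genes changed by 1 on the log2 scale 36 were recovered in root and 41 in shoot, and of 100 changed by 2 there were 83 in root and 78 in shoot, beside 8 false calls in root and 5 in shoot. A list raised by 0.8 in root was found (adjusted p = 1.37e-27), and 1 of 29 other lists was called by mistake. A slope of -0.5 against gene span put on 1 library, here with a spread of 0.1, was measured as -0.46 before the trend was removed and as -6.1e-04 after. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.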

Results

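The libraries labelled quadruple mutant of the SAUR41 subfamily were compared with Col-0 libraries in the root and in the shoot part of 5-day-old Arabidopsis seedlings, with 2 libraries per genotype and tissue. Values are FPKM, changes are log2 of FPKM plus 1 (mutant over Col-0) with their standard error (SE), and means are given with their SD over 2 libraries. On this scale the change of a gene at low FPKM is smaller than the log2 of its ratio. The p-values measure the spread between these libraries only, since the labels do not say whether the 2 libraries of a group came from separate plantings.

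Among the mutated genes, SAUR72 (AT3G12830; TAIR10 chromosome 3, 4078651 to 4079608) had the largest difference in root. It stood at 23.4 and 31.6 FPKM in the Col-0 roots and at 16.9 and 16.3 FPKM in the roots labelled quadruple mutant, a log2 change of -0.68 (SE 0.19, limma adjusted p = 1). In shoot it stood at 9.41 and 7.57 FPKM in Col-0 and at 4.18 and 3.96 FPKM in the mutant (log2 change -0.90, SE 0.19, adjusted p = 0.0624). SAUR71 (AT1G56150; chromosome 1, 21017385 to 21017939) was mainly a shoot transcript, at 7.91 and 5.22 FPKM in Col-0 and 3.28 and 3.02 FPKM in the mutant (log2 change -0.84, SE 0.27, adjusted p = 0.0929). In root SAUR71 stood at 0.173 and 0.986 FPKM in Col-0 and 0.471 and 0.58 FPKM in the mutant. SAUR41 (AT1G16510; chromosome 1, 5644572 to 5645443) was mainly a root transcript and its values overlapped between genotypes: 7.98 and 7.15 FPKM in Col-0 root, 7.75 and 7.1 FPKM in mutant root, 1.21 and 0.745 FPKM in Col-0 shoot, and 1.09 and 0.845 FPKM in mutant shoot. SAUR40 (AT1G79130; chromosome 1, 29771278 to 29771887) was close to absent: it was not listed in the Col-0 roots or in mutant root replicate 1, and stood at 0.073 FPKM in mutant root replicate 2. In shoot SAUR40 stood at 0.099 and 0.0561 FPKM in Col-0 and was not listed in the mutant. Of the 3 mutated genes that were tested, 0 passed the limma threshold of 0.05 in either tissue. SAUR72 in shoot passed without Col-0 shoot replicate 1 (log2 change -0.76, adjusted p = 0.0112) and after the gene length trend described further on was removed (-0.77, adjusted p = 0.045). An FPKM over a whole gene does not show which part of it was read. The positions of the insertions or edits in the mutant are not given in the sources used here, so a transcript broken by its mutation may still count in full.

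**Figure D1:**
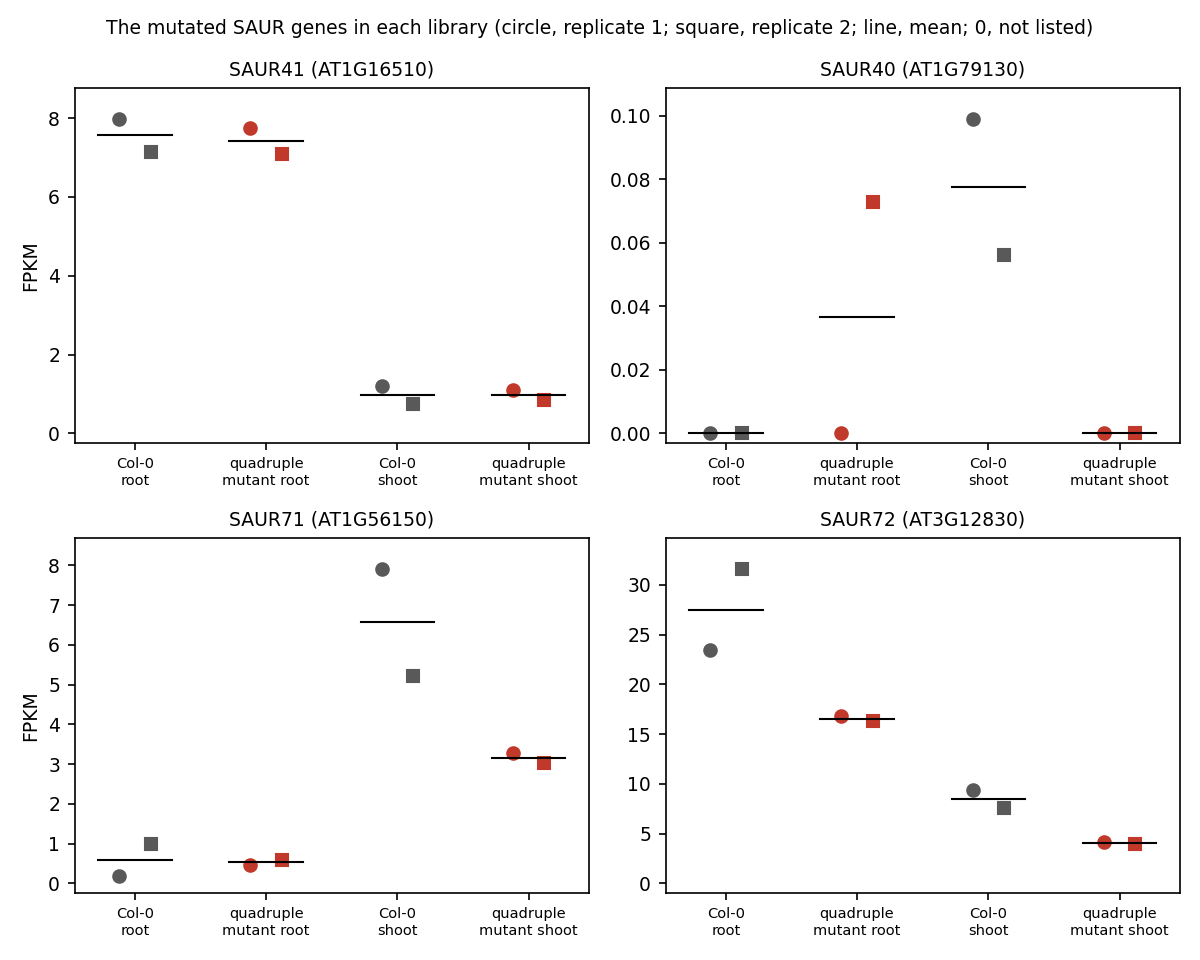
FPKM of SAUR41, SAUR40, SAUR71 and SAUR72 in each of the 8 libraries, by genotype and tissue, on linear axes. Both mutant shoots lay below both Col-0 shoots for SAUR72 (4.18 and 3.96 against 9.41 and 7.57 FPKM) and SAUR71 (3.28 and 3.02 against 7.91 and 5.22 FPKM), while SAUR41 overlapped in both tissues.

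In root, 2 genes rose in the mutant. PI4KG3 (AT5G24240), named for a phosphatidylinositol 4-kinase of the gamma type, rose from 1.79 ± 0.618 FPKM in Col-0 to 38.2 ± 0.0756 FPKM in the mutant (log2 change 3.83, SE 0.18, adjusted p = 0.00276). HEI10 (AT1G53490), whose RING-finger protein acts in meiotic crossover formation, rose from 1.97 ± 0.146 to 10.2 ± 0.355 FPKM (log2 change 1.92, SE 0.13, adjusted p = 0.0179). The files give 1 merged locus to genes that overlap, and both genes lie in such a locus. PI4KG3 shares chromosome 5, 8228892 to 8234652 with AT5G24230 and AT5G24250, and HEI10 shares chromosome 1, 19963047 to 19969757 with MRD1 and RHM2. The abundant neighbours stayed close to their Col-0 values in root: AT5G24230 stood at 15 and 14 FPKM in Col-0 and 14.8 and 12.8 FPKM in the mutant, and RHM2, a UDP-rhamnose synthase gene, at 29.6 and 28.2 against 29.3 and 28.8 FPKM. MRD1 was not listed in the Col-0 roots and stood at 0.711 and 0.531 FPKM in the mutant roots. Since it is not known here whether the libraries kept the strand, reads may have been assigned to the wrong gene within each locus.

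Of 19985 genes tested in root, 2 rose and 0 fell at a limma adjusted p under 0.05, with 514 genes at an unadjusted p under 0.05 (198 higher and 316 lower). The median change of all genes was -0.00. Both mutant values lay above both Col-0 values for 4089 genes and below them for 4568 genes. That is 43.3% of the genes, against the 33.3% that chance gives on average. All genes share the same 4 libraries, so single libraries can move this share and it is not a test. Neither PI4KG3 nor HEI10 passed in root without mutant root replicate 1, where 1 gene fell, or without mutant root replicate 2, where 0 genes passed in limma (371 and 375 at an unadjusted p under 0.05). PI4KG3 passed and HEI10 did not without Col-0 root replicate 1 (1 gene in all), Col-0 root replicate 2 (1 rose and 1 fell), mutant shoot replicate 1 (1 gene) or mutant shoot replicate 2 (1 gene). Both passed among 17 genes without Col-0 shoot replicate 1 and among 17 without Col-0 shoot replicate 2.

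Small shifts of whole groups were seen in root under a preset correlation between genes. The root hair genes were higher in 17 of 17 cases, with a median log2 change of 0.26 (camera adjusted p = 1.2e-14; adjusted p = 0.53 with an estimated correlation). For every other list of this paragraph the adjusted p = 0.716 with an estimated correlation. EXT12, which codes for an extensin of root hairs, went from 24.0 and 22.3 FPKM to 34.1 and 38.1 FPKM (log2 change 0.62, SE 0.14, adjusted p = 1), and PRP1, for a proline-rich wall protein, from 13.2 and 8.93 to 13.4 and 17.0 FPKM (0.44, SE 0.20, adjusted p = 1). The endodermis and suberin genes were higher in 19 of 20 cases (median 0.11, adjusted p = 0.00372; CASP5 0.25, FAR5 0.24). The xyloglucan endotransglucosylases (median 0.11, adjusted p = 0.0259), with XTH13 from 5.04 and 4.66 to 7.16 and 7.83 FPKM (0.54) and XTH12 (0.37), shifted the same way. So did the xylem and secondary wall genes (median 0.12, adjusted p = 0.0259; XCP2 0.25, XCP1 0.21) and the genes of cell wall polysaccharide synthesis and pectin modification (median 0.07, adjusted p = 0.0162; PME68 0.37, PME2 0.29). The class III peroxidases (median 0.04, adjusted p = 0.0175; PER60 0.38, PER7 0.29) and the iron deficiency genes (median 0.04, adjusted p = 0.0255) were also shifted upward. In the iron list CYP82C4, needed for coumarin synthesis under iron shortage, went from 4.39 and 3.96 to 7.21 and 6.92 FPKM (0.64, SE 0.11). It alone passed when adjusted over the list alone, against 0 over all genes. The plasma membrane H+-ATPases and PP2C.D phosphatases had a median of 0.03 (adjusted p = 0.0356; AHA7 0.43, AHA8 0.35).

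Other groups shifted downward in root, and for each of them the adjusted p = 0.716 with an estimated correlation. The rapid touch, wound and cold genes were lower in 18 of 20 cases (median -0.27, camera adjusted p = 6.3e-04; adjusted p = 0.716 with an estimated correlation): the ethylene response factors ERF5 and ERF6 went from 53.0 and 52.0 to 35.4 and 38.8 FPKM (-0.49, SE 0.25) and from 50.8 and 51.3 to 33.0 and 39.6 FPKM (-0.49, SE 0.26). The calmodulins and calmodulin-like proteins were lower in 20 of 23 cases (median -0.20, adjusted p = 6.72e-04; CML43 -0.43, CML23 -0.38). The abscisic acid response genes were lower in 28 of 35 cases (median -0.15, adjusted p = 0.017), with LTI78 from 15.3 and 10.2 to 6.69 and 6.04 FPKM (-0.88, SE 0.46) and RD22 at -0.46. The early auxin response genes (median -0.08, adjusted p = 0.0259, 25 of 32 lower; IAA13 -0.33, IAA3 -0.32) and the other SAUR genes (median -0.06, adjusted p = 0.0449; AT2G21210 -0.43, AT5G53590 -0.31) were shifted less. Apart from CYP82C4, 0 members of these 13 lists passed in limma when adjusted over the list alone, and 0 over all genes.

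The shifts in root were small beside the way genes of a list vary together. With an estimated correlation 0 of the 13 lists passed in camera. Of the 13, only root hair passed without mutant root replicate 1, 6 passed without Col-0 root replicate 2, 7 without Col-0 root replicate 1, and 8 without Col-0 shoot replicate 1 or replicate 2. After removal of the gene length trend 8 of the 13 passed. Those lost then were calmodulins (adjusted p = 0.0532), early auxin response (0.0611), xylem (0.0504), H+-ATPases and phosphatases (0.498) and other SAUR genes (0.856). The remaining lists did not pass in root: calcium and sodium transport (adjusted p = 0.0571), flavonoid and anthocyanin (0.111), phosphate starvation and nitrate response (0.123), salicylate and pathogen response (0.154), expansins (0.188), glucosinolates (0.191), root tissue (0.191), auxin transport (0.243), circadian clock (0.243), aquaporins (0.249), ethylene (0.358), photosynthetic tissue (0.459), gibberellin and brassinosteroid (0.468), jasmonate (0.468), stomatal lineage (0.468), heat shock proteins (0.721) and cell cycle (0.961).

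Both genes that rose in root also rose in shoot. PI4KG3 went from 0.0547 ± 0.0145 FPKM in Col-0 shoot to 12.1 ± 0.468 FPKM in mutant shoot (log2 change 3.63, SE 0.18, adjusted p = 0.00396), and HEI10 from 0.38 ± 0.0896 to 3.92 ± 0.24 FPKM (1.84, SE 0.13, adjusted p = 0.0166). After removal of the gene length trend HEI10 passed in neither tissue: its change was 1.79 in root (SE 0.23, adjusted p = 0.261) and 1.11 in shoot (SE 0.23, adjusted p = 0.0524). In root its call ended with the larger SE, and the span used for it is that of the merged locus. AT2G01422 (chromosome 2, 183940 to 184734), a non-coding RNA gene, moved the other way: it fell in shoot from 28.2 ± 4.78 to 7.07 ± 0.689 FPKM (-1.85, SE 0.18, adjusted p = 0.0387). In root AT2G01422 stood at 42.6 and 41.6 FPKM in Col-0 against 8.78 and 11.2 FPKM in the mutant (-1.98, SE 0.18, adjusted p = 0.0819), short of the threshold. It passed in both tissues after removal of the trend (-1.82 in root, adjusted p = 0.0357; -1.66 in shoot, adjusted p = 0.0231), so that PI4KG3 and AT2G01422 were then the 2 genes that passed in root. The overlap of 2 genes that rose in both tissues compared with 0.0192 expected if the tissues were independent (1-sided Fisher exact p = 9.18e-05). In the fit the tissues share 1 spread per gene, so a gene with a small spread is favoured in both and this p may overstate the overlap. With each tissue fitted alone 0 genes passed in shoot, so that 0 were shared. As fitted, 0 genes fell in both. Changes in root and shoot were correlated across the 19985 genes (Pearson r = 0.34, Spearman rho = 0.37) and more so across the 9789 genes at 5 FPKM or more in both tissues (0.48 and 0.51), although genes are not independent replicates. Both sets of changes followed gene span (Spearman rho 0.56 in root and 0.63 in shoot), and after removal of the length trend the correlations were 0.23 and 0.24 across all genes and 0.29 and 0.28 across those at 5 FPKM or more. The overlap was 1 gene without Col-0 root replicate 1 or replicate 2, 0 without any 1 of the mutant libraries, 7 without Col-0 shoot replicate 1 and 9 without Col-0 shoot replicate 2.

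**Figure D2:**
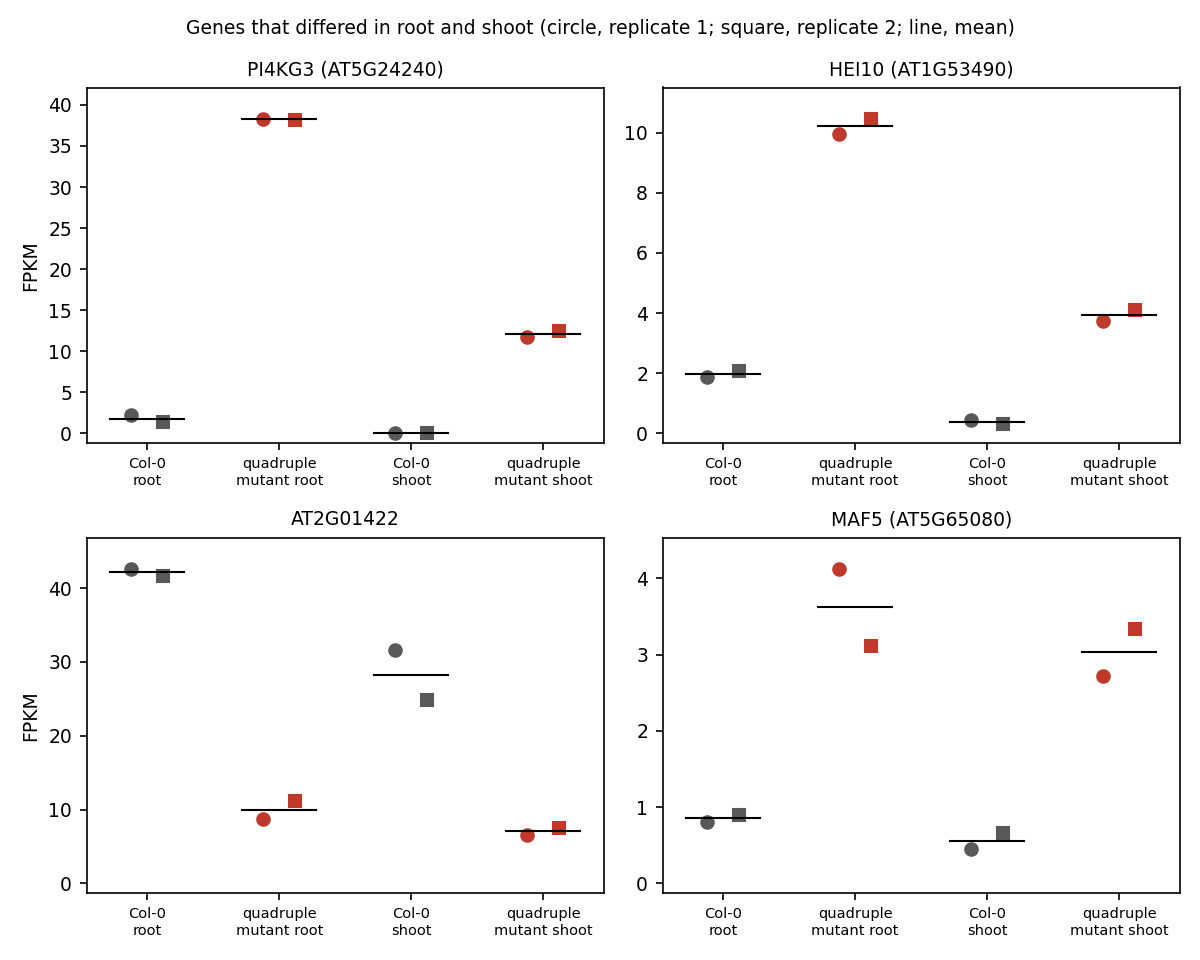
FPKM of PI4KG3, HEI10, AT2G01422 and MAF5 in each of the 8 libraries, by genotype and tissue, on linear axes. PI4KG3 stood at 38.3 and 38.2 FPKM in the mutant roots against 2.23 and 1.36 FPKM in the Col-0 roots, and AT2G01422 at 8.78 and 11.2 against 42.6 and 41.6 FPKM; MAF5 was chosen after its values were seen.

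In shoot, 9 of the largest increases beside PI4KG3 were as follows. WRKY18 (AT4G31800; chromosome 4, 15383201 to 15385029), a transcription factor of the pathogen response, rose from 7.55 ± 2.38 to 42.0 ± 14.3 FPKM (log2 change 2.32, SE 0.33, adjusted p = 0.0466). FAMT, a farnesoic acid methyltransferase gene, rose from 4.76 ± 2.25 to 25 ± 8.69 FPKM (2.19, SE 0.33, adjusted p = 0.0479). AT5G05600, whose product hydroxylates jasmonate, rose from 7.11 and 9.78 to 38.9 and 41.9 FPKM (2.14, SE 0.19, adjusted p = 0.0387), and AT3G09830 from 2.33 and 5.40 to 17.3 and 21.7 FPKM (2.14, SE 0.30, adjusted p = 0.0466). XTH18 (chromosome 4, 14825808 to 14827047), a xyloglucan endotransglucosylase gene, rose from 11 and 11.3 to 40.8 and 65.4 FPKM (2.12, SE 0.23, adjusted p = 0.0447). PXG3 (AT2G33380; chromosome 2, 14144831 to 14146471), the dehydration gene also called RD20, rose from 4.27 ± 0.856 to 21.6 ± 0.646 FPKM (2.11, SE 0.15, adjusted p = 0.0166). ILL4, an amidohydrolase gene of the family that splits auxin and jasmonate conjugates, rose from 7.31 and 13.6 to 40.6 and 47.5 FPKM (2.03, SE 0.25, adjusted p = 0.0452). HIR3 rose from 3.3 and 5.02 to 14.8 and 25.1 FPKM (2.00, SE 0.26, adjusted p = 0.046). TIFY7 (AT1G70700, also called JAZ9; chromosome 1, 26654768 to 26657064), a repressor of jasmonate signalling, rose from 88.1 ± 33.9 to 342 ± 32.7 FPKM (2.00, SE 0.26, adjusted p = 0.046).

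Fewer genes fell in shoot. AT2G15020 fell from 28.8 and 24.8 to 13.3 and 10.2 FPKM (log2 change -1.13, SE 0.16, adjusted p = 0.047), CML36, a calmodulin-like gene, from 8.31 and 8.06 to 3.53 and 3.72 FPKM (-0.99, SE 0.12, adjusted p = 0.0452), and MARD1 from 15.3 and 15.5 to 7.32 and 7.82 FPKM (-0.94, SE 0.13, adjusted p = 0.0466). AT3G13310, a DnaJ-type chaperone gene, fell from 13.7 and 12.3 to 7.11 and 6.76 FPKM (-0.82, SE 0.11, adjusted p = 0.046). UGT75D1, a glucosyltransferase gene, fell from 29.7 and 30.7 to 18.9 and 16.4 FPKM (-0.74, SE 0.12, adjusted p = 0.0479), and LBD37, a nitrogen-responsive repressor of anthocyanin synthesis, from 79.4 and 75.6 to 47.2 and 51.1 FPKM (-0.65, SE 0.10, adjusted p = 0.0479).

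The median change of all 19985 genes in shoot was 0.31, and 75.6% of the changes were positive. Relative to that median, WRKY18 changed by 2.01, TIFY7 by 1.68, PXG3 by 1.80, LBD37 by -0.96 and CML36 by -1.31. In limma 192 genes rose and 12 fell (151 of the 204 by at least 2-fold), with 7738 genes at an unadjusted p under 0.05 (7035 higher and 703 lower). The split depended on the treatment of the libraries: 262 rose and 210 fell after quantile normalization within the tissue, 440 and 151 after removal of the gene length trend, and 1326 and 1360 after median-ratio rescaling without Col-0 shoot replicate 1. Both mutant values lay above both Col-0 values for 11355 genes and below them for 1894 genes. That is 66.3%, against the 33.3% that chance gives on average. As in root, single libraries can move this share, and it is not a test. When each library was rescaled by its median ratio within the tissue, 15 genes rose and 2 fell. Of the 204 genes 16 passed then, all 204 with the same sign as before. Those that passed then were ILL6, ILL4, HEI10, TIFY7, OPR3, PXG3, AT2G38240, AT3G22275, SSL7, XBAT34, AT5G05600, TIFY9, PI4KG3, PNC2 and HAI1 (higher) and RPL33 (lower), while AT5G02760 passed (lower) only after rescaling. The median change of the 192 genes that rose was 1.24 and that of the 12 that fell -0.89. The number of genes that passed in shoot was 5208 without Col-0 shoot replicate 1 and 13209 without Col-0 shoot replicate 2, against 1, 1, 0 and 0 without the 4 root libraries in turn (Col-0 first) and 0 and 2 without mutant shoot replicates 1 and 2. Of the 204 genes 0 passed with each tissue fitted alone, 0 with the replicate block and 2 with a pseudocount of 0.1.

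Of the lists tested in shoot, the jasmonate genes had the largest median change. All 20 tested members were higher in the mutant, with a median log2 change of 1.54, or 1.23 above that of all genes (camera adjusted p = 4.34e-09; adjusted p = 0.472 with an estimated correlation). Members of jasmonate synthesis rose: AOC3 (chromosome 3, 9409290 to 9410567) from 9.52 and 12.2 to 34.0 and 56.3 FPKM (1.93, SE 0.25, adjusted p = 0.046), AOC1 from 28.5 and 31.8 to 78.1 and 101 FPKM (1.53, SE 0.20, adjusted p = 0.0452) and OPR3 from 56.2 and 85.0 to 241 and 256 FPKM (1.83, SE 0.19, adjusted p = 0.0447). So did the repressors of the pathway: TIFY9 (also called JAZ10; chromosome 5, 4218888 to 4220883) from 8.83 and 11.4 to 39.8 and 45.8 FPKM (1.99, SE 0.19, adjusted p = 0.0387), TIFY11A (JAZ5) from 9.80 and 13.6 to 39.9 and 52.7 FPKM (1.90, SE 0.24, adjusted p = 0.0452), TIFY10A (JAZ1; 1.38, adjusted p = 0.0479), TIFY10B (JAZ2; 1.46, adjusted p = 0.0387) and TIFY11B (JAZ6; 1.36, adjusted p = 0.0447). VSP1, a vegetative storage protein gene induced by jasmonate, rose from 3.93 and 4.28 to 14.1 and 18.1 FPKM (1.74, SE 0.20, adjusted p = 0.0447). LOX3 (1.67, adjusted p = 0.0633), LOX4 (1.74, adjusted p = 0.0633), LOX2 (0.78, adjusted p = 0.0968), VSP2 (0.97, adjusted p = 0.0724), AOC2 (0.76, adjusted p = 0.0663) and MYC2 (0.54, adjusted p = 0.0958) did not pass. After removal of the length trend LOX2 stood at 0.01 (adjusted p = 0.978), MYC2 at 0.21, LOX3 at 0.87 and LOX4 at 0.92, while AOC2 passed (0.86, adjusted p = 0.0436). Of the repressors, TIFY5A (JAZ8, 1.55, limma adjusted p = 0.0561) and TIFY 5B (JAZ7, 1.57, adjusted p = 0.0562) did not pass as deposited. Both passed after removal of the trend (limma adjusted p = 0.0371 and 0.0301). CLH1 did not pass as deposited (0.52, adjusted p = 0.0852). CYP74A, the allene oxide synthase gene, stood at 425 and 299 against 371 and 410 FPKM (0.13, adjusted p = 0.639). AOC1, AOC2 and AOC3, like VSP1 and VSP2, are close copies whose reads may be shared. In limma 10 members rose over all genes, and 19 when adjusted over the list alone. In root the list had a median of 0.02 and 0 members passed over all genes or over the list alone.

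The jasmonate list also passed camera in shoot under other treatments of the libraries, but not with an estimated correlation between its members. The list median was 1.1 after rescaling within the tissue (adjusted p = 4.8e-09), 1.23 after removal of the gene length trend (adjusted p = 4.53e-12, with 13 members rising) and 1.31 without Col-0 shoot replicate 1 (adjusted p = 4.78e-09). The list had an adjusted p = 0.472 with an estimated correlation. It had an adjusted p = 0.0131 in the self-contained test fry, which no other of the 30 lists passed in shoot.

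**Figure D3:**
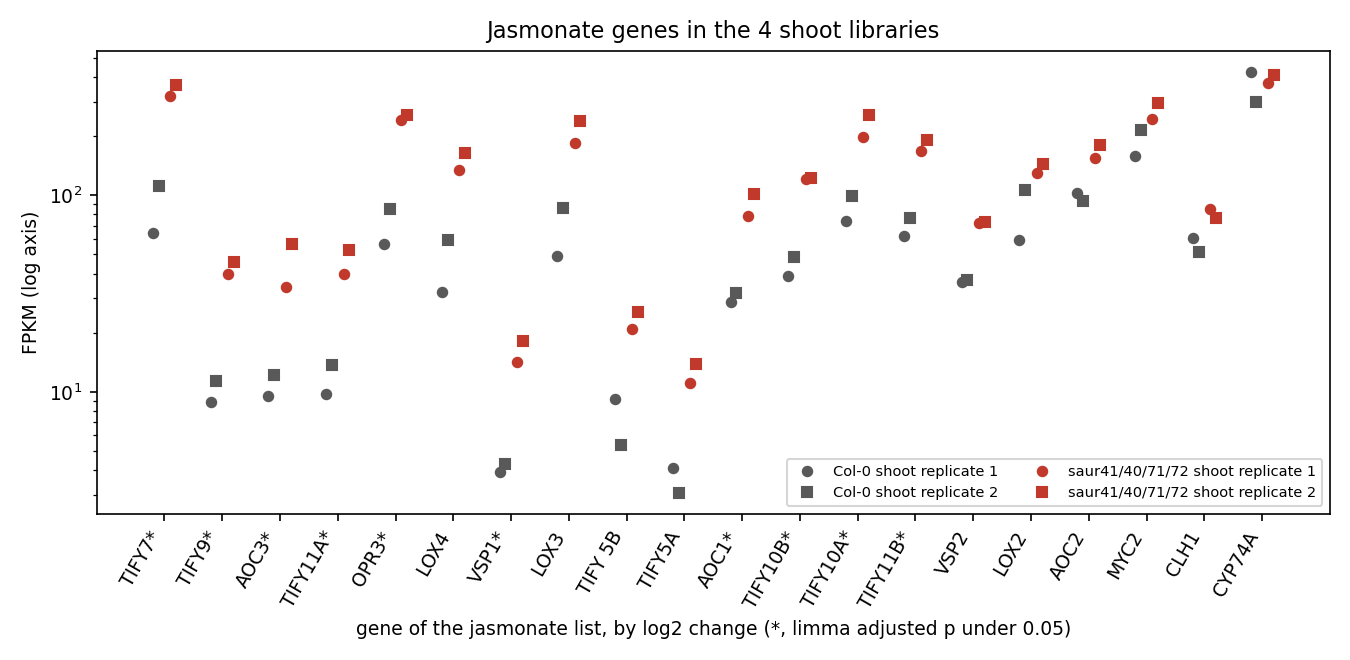
FPKM of the 20 tested jasmonate genes in the 4 shoot libraries, on a log axis and ordered by log2 change. TIFY7 stood at 319 and 365 FPKM in the mutant shoots against 64.2 and 112 FPKM in the Col-0 shoots, while the values of CYP74A overlapped (371 and 410 against 425 and 299 FPKM).

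Genes of the abscisic acid response were also higher in shoot, with a median of 0.81 or 0.50 above all genes (camera adjusted p = 6.41e-04; adjusted p = 0.546 with an estimated correlation). Beside PXG3, the phosphatase gene HAI1 rose from 3.61 and 5.43 to 15.3 and 16.3 FPKM (1.62, SE 0.19, adjusted p = 0.0447), AFP3 from 7.26 and 8.23 to 16.9 and 17.5 FPKM (1.06, SE 0.14, adjusted p = 0.046) and the galactinol synthase gene GOLS2 from 2.98 and 2.95 to 6.73 and 6.89 FPKM (0.98, SE 0.14, adjusted p = 0.0466). Of the 35 tested members 31 were higher and 4 lower: TSPO (-0.55, adjusted p = 0.164), RAB18 (23.3 ± 1.81 to 16.8 ± 1.97 FPKM, -0.45, adjusted p = 0.145), RD22 (-0.31, adjusted p = 0.328) and LEA4-5 (-0.08, adjusted p = 0.746). In limma 4 members rose over all genes and 25 when adjusted over the list alone. The calcium and sodium transport genes had a median of 0.85, or 0.54 above all genes, with 21 of 22 higher (adjusted p = 0.00824; adjusted p = 0.662 with an estimated correlation). CAX1, a vacuolar calcium exchanger gene, rose from 21.5 and 35.4 to 83.5 and 85.4 FPKM (1.58, SE 0.22, adjusted p = 0.0466), and it alone passed over all genes against 12 over the list alone. These are long genes (median span 4344.5 bp, against 2403 bp for all tested genes), and the list no longer passed after removal of the length trend (median 0.09, adjusted p = 0.281). Without Col-0 shoot replicate 1 its median was 0.35 (adjusted p = 0.00151).

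Lower lists in shoot were led by the photosynthetic genes. Their median was -0.37, or -0.69 relative to all genes, with 29 of 32 lower (camera adjusted p = 7.53e-17; adjusted p = 0.503 with an estimated correlation), and 0 passed in limma over all genes or over the list alone. Without Col-0 shoot replicate 1 the median was -0.12 against 0.17 for all genes. In that library the list without LHCB1.3 took 26.6% of all FPKM, against 20.3% in replicate 2. RBCS-1B, a Rubisco small subunit gene, stood at 2863 and 2012 FPKM in Col-0 and 1639 and 1326 FPKM in the mutant (-0.70, SE 0.20, adjusted p = 0.0825). LHCB1.3 was not listed in Col-0 shoot replicate 1 and stood at 21258 FPKM in replicate 2 and at 16938 and 15861 FPKM in the mutant shoots, so that its fitted change of 6.81 rests on a missing value; it was -0.38 without Col-0 shoot replicate 1. The expansins were lower (median -0.26, or -0.58 relative to all genes, adjusted p = 4.45e-08; adjusted p = 0.421 with an estimated correlation), although EXLA1 rose from 7.32 and 8.24 to 28.7 and 29.6 FPKM (1.78, SE 0.20, adjusted p = 0.0447); 2 members rose and 4 fell when adjusted over the list alone. Without Col-0 shoot replicate 1 their median was -0.11 (adjusted p = 1.68e-05). The aquaporins were lower in 15 of 19 cases (median -0.19, or -0.50 relative to all genes, adjusted p = 1.31e-06; adjusted p = 0.546 with an estimated correlation), with TIP1-2 (-0.48, adjusted p = 0.104) and TIP2-1 (-0.40, adjusted p = 0.161). Without Col-0 shoot replicate 1 the aquaporin median was 0.01, so that the list was lower only relative to all genes (adjusted p = 0.0463). The other SAUR genes had a median of -0.07, or -0.38 relative to all genes (adjusted p = 1.98e-09; adjusted p = 0.421 with an estimated correlation). AT4G38860 stood at 30 and 23.4 against 14.7 and 10.9 FPKM (-1.01, SE 0.20, adjusted p = 0.0583) and AT4G34760 at 17.7 and 12.2 against 9.49 and 6.22 FPKM (-0.85, SE 0.26, adjusted p = 0.0861). SAUR genes are short (median span 645 bp) and alike in sequence. This list had a median of 0.01 without Col-0 shoot replicate 1 (adjusted p = 3.18e-05, downward relative to all genes) and did not pass after removal of the length trend (adjusted p = 0.767).

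The remaining lists that passed in shoot were lower only relative to all genes. Auxin transport had a median of 0.12 and a mean of 0.07, but the test was downward (adjusted p = 0.042; adjusted p = 0.546 with an estimated correlation). After removal of the length trend its median was -0.39 (adjusted p = 9.8e-05). The endodermis and suberin genes (median 0.00, mean 0.03) had an adjusted p = 0.0101, and the root hair genes (median 0.00, mean 0.03) an adjusted p = 0.0154; for both, the adjusted p = 0.546 with an estimated correlation. Neither passed after rescaling within the tissue (adjusted p = 0.266 and 0.949). Of the root hair genes 0 of 17 reached a mean of 1 FPKM in shoot, and of the endodermis and suberin genes 8 of 20. In limma 0 members of these 3 lists passed, over all genes or over the list alone.

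The other lists did not pass in shoot, though some members did. Counts over the list alone in shoot, here and above, include the shift of all genes. In limma 7035 of 19985 genes were higher and 703 lower in shoot at an unadjusted p under 0.05. In the xyloglucan endotransglucosylases (camera adjusted p = 0.778) XTH23 rose from 6.14 and 5.70 to 17.1 and 19.8 FPKM (1.49, adjusted p = 0.0447) and XTH24 from 19.1 and 16.5 to 34.3 and 37.7 FPKM (0.98, adjusted p = 0.0466), with 3 rising over all genes and 7 over the list alone. CML49 (1.17, adjusted p = 0.0451) and CML9 (0.95, adjusted p = 0.0479) rose among calmodulins and calmodulin-like proteins (0.327), with 6 over the list alone. PER71 (1.31, adjusted p = 0.0496) rose among class III peroxidases (0.0611, with 3 over the list alone). MYB34, a regulator of indole glucosinolates, rose from 19.1 and 25.8 to 61.0 and 56.3 FPKM (1.36, adjusted p = 0.0447) among glucosinolates (0.0955, with 7 over the list alone). LBD37 fell among phosphate starvation and nitrate response (0.0611, with 4 rising and 3 falling over the list alone). Of the plasma membrane H+-ATPases and PP2C.D phosphatases (0.235) 7 rose and 1 fell over the list alone and 0 over all genes; PP2C6 stood at 10.2 ± 3.19 against 22.7 ± 1.26 FPKM (1.11, adjusted p = 0.0575). In early auxin response (0.318, with 3 over the list alone) IAA2 stood at 13.5 and 22.5 against 42.0 and 58.8 FPKM (1.46, adjusted p = 0.0539). Adjusted over the list alone, 6 members rose and 1 fell in each of salicylate and pathogen response (10 tested, camera adjusted p = 0.33), rapid touch, wound and cold response (20 tested, 0.0611) and circadian clock (19 tested, 0.695), with 0 over all genes. In the same way 3 rose and 2 fell in cell wall polysaccharide synthesis and pectin modification (0.6), 3 rose in gibberellin and brassinosteroid (0.0611), 1 rose in heat shock proteins (0.33), 1 rose in flavonoid and anthocyanin (0.209) and 1 fell in cell cycle (0.449). In the remaining lists 0 members passed over the list alone: adjusted p was 0.557 for ethylene, 0.0611 for iron deficiency, 0.131 for root tissue, 0.108 for xylem and secondary wall and 0.25 for stomatal lineage.

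**Figure D4:**
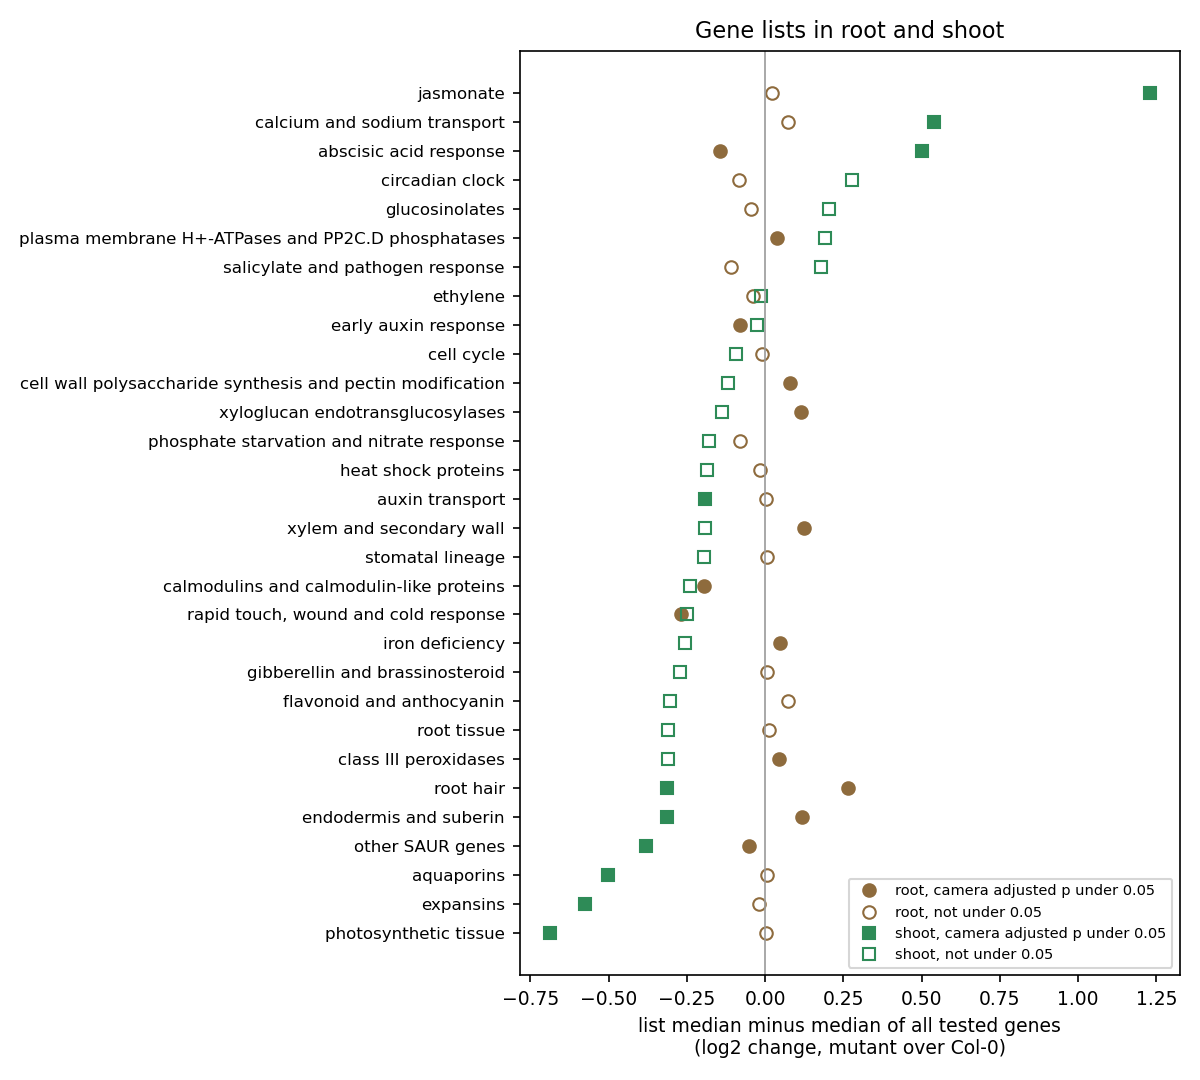
Median log2 change of each list in root and shoot, mutant over Col-0, minus the median of all tested genes of that tissue. In shoot the jasmonate list lay furthest up at 1.23 and the photosynthetic genes furthest down at -0.69, and in root the root hair genes lay furthest up at 0.26.

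Whether the mutant changed more in 1 tissue than in the other was tested gene by gene as an interaction. The jasmonate repressor TIFY7, at 2.56 and 2.06 FPKM in Col-0 root and 2.66 and 2.33 FPKM in mutant root, had an interaction adjusted p = 0.247, as did WRKY18 (0.25) and XTH18 (0.247). PI4KG3 (0.626) and HEI10 (0.788) changed in both tissues. In limma 0 genes passed for the interaction, with 3094 at an unadjusted p under 0.05 and a smallest adjusted p of 0.247. The median of the interaction was -0.34. The number that passed was 1 without Col-0 root replicate 2, 2066 without Col-0 shoot replicate 1, 11549 without Col-0 shoot replicate 2 and 2 without mutant shoot replicate 2.

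The 2 tissues were far apart in Col-0. RBCS-1A, a Rubisco small subunit gene, stood at 19.6 ± 1.41 FPKM in root and 17780 ± 4671 FPKM in shoot (log2 root over shoot -9.73, SE 0.19, adjusted p = 1.43e-07), LHCB2.1, of the light-harvesting antenna, at 8.22 ± 1.51 and 5388 ± 1224 FPKM (-9.18, SE 0.20, adjusted p = 1.86e-07), and the aquaporin gene TIP2-1 at 72.9 and 57.8 FPKM in root and 1852 and 1297 FPKM in shoot (-4.56). In the other direction BGLU23, the beta-glucosidase of ER bodies also called PYK10, stood at 5737 ± 262 FPKM in root and 622 ± 39.0 FPKM in shoot (3.21, SE 0.12, adjusted p = 5.67e-07), EXT12 at 23.2 ± 1.22 and 0.0563 ± 0.0797 FPKM (4.52) and CASP5, of the Casparian strip, at 6.63 ± 1.46 and 0.139 ± 0.197 FPKM (2.74). The iron transporter gene IRT1 stood at 12.8 ± 0.136 FPKM in root and was not listed in shoot. The photosynthetic list without LHCB1.3 took 0.0916% and 0.0905% of all FPKM in the Col-0 roots and 0.0972% and 0.0969% in the mutant roots. In shoot it took 26.6% and 20.3% in Col-0 and 18.8% and 17.5% in the mutant. In limma 14419 genes were higher in root and 2999 higher in shoot (13963 of them by at least 2-fold), with a median of 1.23. After median-ratio rescaling over all libraries the split was 6505 and 6148.

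Col-0 shoot replicate 1 stood apart from the other shoot libraries in these same gene groups. It gave the photosynthetic list without LHCB1.3 26.6% of its FPKM. It listed 21355 genes against 21862, 22360 and 22477 in the other shoots, and had a median listed value of 3.33 FPKM against 5.02, 5.76 and 5.87. The 2 Col-0 shoots correlated at r = 0.957 with a median absolute difference of 0.40, against r of 0.994, 0.995 and 0.994 and differences of 0.11, 0.09 and 0.09 in Col-0 root, mutant root and mutant shoot. The difference followed the span of the gene. Over 9357 genes with a locus of their own and at 5 FPKM or more in shoot, Col-0 shoot replicate 2 minus replicate 1 had a Spearman rho of 0.73 with gene span, and its median went from -0.31 in the shortest of 5 classes (median span 1130 bp) through 0.03, 0.28 and 0.59 to 1.1 in the longest (4503 bp). In the mutant shoots the same difference had a rho of 0.11. The mutant over Col-0 changes had a rho with span of 0.63 in shoot and 0.56 in root, so that long genes were on average higher in the mutant than short ones in both tissues. Against Col-0 shoot replicate 2 alone the mutant shoots had a rho of 0.279 and 0.274, so the value in shoot rests largely on replicate 1. In root the single pairs of mutant and Col-0 libraries had a rho between 0.367 and 0.513. Of the 204 genes that passed in shoot 163 also passed after this trend was removed.

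**Figure D5:**
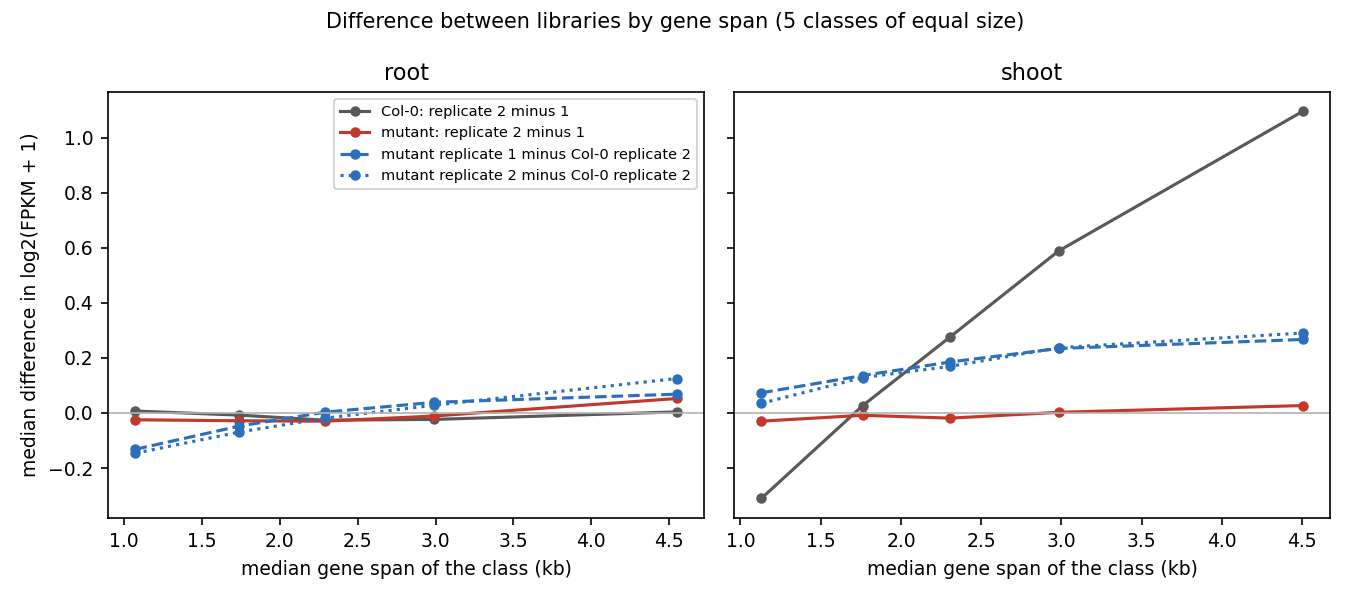
Median difference between libraries in log2 of FPKM plus 1 against the median gene span of 5 classes of equal size (kb), in root and shoot, for genes with a locus of their own. Col-0 shoot replicate 2 minus replicate 1 went from -0.31 to 1.1, while mutant shoot replicate 2 minus replicate 1 went from -0.03 to 0.03.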

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

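All tests in this part, and the test of lists for the interaction, were chosen after the results were seen. With 2 libraries per group a test for a single library far from its group is not defined.

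By camera on the interaction 17 of the 30 lists had an adjusted p under 0.05, 12 higher and 5 lower in root relative to shoot. In order of p these were photosynthetic genes (adjusted p = 6.16e-14), root hair (3.26e-11), jasmonate (1.14e-10), expansins (1.13e-09), aquaporins (8.42e-08), other SAUR genes (6.81e-07), abscisic acid response (1.28e-06) and endodermis and suberin (9.77e-06). Further down came iron deficiency (3.68e-04), class III peroxidases (7.15e-04), xylem and secondary wall (0.00291), auxin transport (0.00313), glucosinolates (0.0159), root tissue (0.0159), flavonoid and anthocyanin (0.0371), early auxin response (0.0389) and calcium and sodium transport (0.0452). By median relative to all genes the jasmonate list differed most (-1.16), against 0.67 for photosynthetic genes. For root hair the test says nothing of a difference between tissues, since 0 of its 17 members reached a mean of 1 FPKM in shoot. The same limit bears on root tissue (2 of 14 members), iron deficiency (6 of 18), endodermis and suberin (8 of 20) and class III peroxidases (16 of 36). With an estimated correlation 0 of the lists passed in camera (smallest adjusted p = 0.313), and 10 of the 17 passed after removal of the gene length trend.

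The jasmonate genes were higher in mutant shoot, with a median change of 0.02 in root. Their median stayed 1.1 above that of all genes after rescaling within the tissue (SE 0.16). The SE of a median, here and in the rest of this part, is the spread over the genes of the set. It treats genes as independent, although those of the jasmonate list had an estimated correlation of 0.25. It also leaves out the variation between libraries, so it understates the uncertainty. Rescaling moves all genes of a library alike, so it could hardly have lowered this difference and decides nothing on scaling. After removal of the length trend their median stayed 1.21 above that of all genes (SE over genes 0.17), against 1.23 as deposited. The list has a median span of 1775 bp, against 2403 bp for all tested genes, and the trend raised long genes in the mutant. Its removal could therefore hardly have lowered the median of the list and is a weak test. A trend of this direction would not by itself lift such a list above all genes, which argues against it as the whole cause. Handling of the plants at harvest stays open. After removal of the trend the rapid touch, wound and cold genes had a median of 0.022 relative to all genes (SE 0.21). Single members lay between -0.92 and 1.73. The highest was TIFY5A, which is also in the jasmonate list, so its value does not speak for handling. As deposited 6 members rose and 1 fell when adjusted over the list alone. The shift of all genes in shoot could give such counts, since 7035 of 19985 genes were higher and 703 lower in limma at an unadjusted p under 0.05. A change of jasmonate signalling in the mutant shoot may explain the shift and was not tested apart from handling.

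Genes at an unadjusted p under 0.01 in both tissues numbered 12, all differing in the same direction in root and shoot (7 up and 5 down). Of these, 7 lie on a chromosome without a mutated gene, as do 54.1% of the tested genes. Only 1, HEI10, lies within 2 Mb of a mutated gene (8.33% against 16% of the tested genes, 1-sided Fisher exact p = 0.871). Linkage stays open for HEI10, which is 1.05 Mb from SAUR71. It is also not excluded for AT1G27110, AT1G67105 and AT3G29644, which lie 3.77, 4.04 and 7.42 Mb from the nearest mutated gene. The 7 genes on other chromosomes argue against linked segments as the whole cause for the 12 genes. After removal of the length trend their median change in the direction of each gene was 0.84 relative to all genes (SE 0.31), with 8 of the 12 still under 0.01 in both tissues, so that a part of the trend in the smaller changes cannot be told apart; PI4KG3 still changed by 3.09 in shoot, which argues against the trend for this gene. A candidate explanation is an unlinked difference between the seed stocks, which was not tested, and an effect of the mutated genes stays open as well.

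Col-0 shoot replicate 1 lay apart from the other 3 shoot libraries. Lower depth is argued against, since the depth of replicate 2 was 0.889 times that of replicate 1. Under-counting of long genes is a candidate explanation: replicate 2 minus replicate 1 had a Spearman rho of 0.73 with gene span across genes, against at most 0.185 for the other pairs of replicates. A larger share of photosynthetic tissue may add to it, as 30 of 31 photosynthetic genes (LHCB1.3 left out) were higher in replicate 1 after removal of the trend (median 0.43, SE 0.15). Neither excludes the other.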

How the results depend on the processing

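With 2 libraries per group each result leans on single libraries, and leaving 1 out leaves a lone sample that is assumed to vary like the other groups. Over the libraries left out in turn, the genes that passed numbered 0 to 17 in root (2 with all), 0 to 13209 in shoot (204 with all) and 0 to 11549 for the interaction (0 with all), and those shared by root and shoot 0 to 9 (2 with all). In shoot the highest number came without Col-0 shoot replicate 2, with 5208 without replicate 1. The lists that passed numbered 1 to 13 in root and 10 to 14 in shoot. SAUR72 in shoot ranged from -1.04 to -0.76 and SAUR71 in shoot from -1.10 to -0.58. The fit shares 1 spread per gene over the 4 groups, and the 2 Col-0 shoots differed most from each other (median absolute difference 0.40). Without either of them the median SE fell from 0.19 to 0.10 in root and to 0.12 in shoot. With each tissue fitted alone it was 0.10 in root and 0.23 in shoot. The calls in shoot thus lean on the smaller spread of the roots, and those in root are held down by the Col-0 shoots. Other causes were not tested. Root against shoot in Col-0 stayed within 1.5 times its count in every setting (12653 to 18594), but the genes and the split did not stay the same. After median-ratio rescaling over all libraries 10646 of the 17418 genes passed again, and the median went from 1.23 to 0.087.

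Genes that passed in root, in shoot and in both numbered 1, 2 and 1 with a pseudocount of 0.1, 1, 28 and 1 with median-ratio rescaling over all libraries, 1, 472 and 1 with quantile normalization, and 8, 0 and 0 with each tissue fitted alone. With no filter on low values 9 passed in root and 17 in shoot. With a pseudocount of 0.5 there were 39 in shoot, with moderation without trend 353, and 1 gene was shared among those at 5 FPKM or more in both tissues. With the replicate block 0 genes passed in root, 0 in shoot and 0 in both, in limma. Libraries of the same number hardly deviated together (correlation across genes 0.043 in root and 0.118 in shoot). This rests on 1 difference per genotype, which in Col-0 shoot followed gene span, so it cannot exclude that the numbers pair the samples. The block also costs degrees of freedom. The lists that passed in root fell to 4 with no filter and to 0 with an estimated correlation or fry, and in shoot to 0 with an estimated correlation and to 1 with fry. SAUR72 in shoot was -1.35 after quantile normalization, where it passed.

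Settings chosen after the data were seen gave 17 genes in shoot with rescaling within the tissue and 591 with the gene length trend removed, where SAUR72 passed at -0.77. Rescaling within the tissue without Col-0 shoot replicate 1 gave 16 genes in root, 2686 in shoot, 518 for the interaction and 6 shared, with SAUR72 at -0.96. Removal of the trend without that library gave 12, 2228, 478 and 4, with SAUR72 at -0.78 and 8 lists in root. LHCB1.3 in shoot (6.81) reversed to -0.38 without Col-0 shoot replicate 1, to -0.61 with rescaling in addition and to -0.42 with the trend removed in addition, since that library does not list it. Of the 72 results for named genes in shoot, 32 had a call. All 32 lost it with each tissue fitted alone, where 0 genes passed in shoot. Of these 32, 24 lost it with rescaling within the tissue and 30 with a pseudocount of 0.1, with the same direction. DESeq2 was not run, since counts were not used here. Sequencing depth is not given in the sources used here, so its limit on low genes could not be set.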

Other observations

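Beside PI4KG3, HEI10 and AT2G01422, 9 genes stood at an unadjusted p under 0.01 in the same direction in root and in shoot. These were looked at after their values were seen, 0 of the 9 passed in root and MAF5 alone passed in shoot. MAF5 (AT5G65080; TAIR10 chromosome 5, 25997504 to 26002465), a relative of the floral repressor FLC, stood at 0.804 and 0.897 FPKM in Col-0 root against 4.12 and 3.12 FPKM in mutant root (log2 change 1.31, SE 0.16, limma adjusted p = 0.327) and rose in shoot from 0.447 and 0.654 to 2.73 and 3.34 FPKM (1.38, SE 0.16, adjusted p = 0.0447). Its neighbour MAF4 (25992243 to 25996174) stood at 1.63 and 2.02 against 4.80 and 3.48 FPKM in root (0.86, adjusted p = 1) and at 1.16 and 0.919 against 2.67 and 2.50 FPKM in shoot (0.82, SE 0.17, adjusted p = 0.0609). After removal of the length trend the shoot change was 0.84 for MAF5 (SE 0.17, adjusted p = 0.0499) and 0.30 for MAF4 (SE 0.25, adjusted p = 0.447). The 2 genes are close copies, and reads of either may have been counted for the other. Lower in the mutant were SADHU5-1, a retroposon pseudogene (7.63 and 9.85 against 3.29 and 3.83 FPKM in root, -1.09, adjusted p = 0.328), and the non-coding RNA genes AT3G29644 (4.90 and 3.65 against 0.381 and 0.77 FPKM in shoot, -1.74, adjusted p = 0.0509) and AT1G67105 (3.81 and 2.41 against 1.13 and 0.978 FPKM in shoot, -0.98, adjusted p = 0.0561), the latter 2 with a root change of -1.29 and -0.70 (adjusted p = 1 for each). The remaining genes of the 12 were AT3G60286, AT2G37540 and AT1G27110 (higher) and GRXS5 (lower). For these 12 genes a median change of 0.84 was left after removal of the length trend, as given above.

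Seed storage and oil body transcripts, whose list had too few tested members for a test, summed to 11.1 and 6.27 FPKM in the Col-0 shoots and 6.02 and 4.80 FPKM in the mutant shoots, and to 1.3 FPKM or less in each root. PER1 (here AT1G48130, a seed peroxiredoxin gene) fell in shoot from 2.03 and 1.62 to 0.789 and 0.546 FPKM (log2 change -0.76, SE 0.12, limma adjusted p = 0.0479). OLEO2, an oleosin gene, stood at 4.25 and 1.80 against 1.15 and 0.487 FPKM (-1.10, SE 0.30, adjusted p = 0.0801). Of the other 2 tested members AT2S1 went the other way (1.35 and 0.370 against 1.54 and 1.96 FPKM, 0.61, adjusted p = 0.118) and OL2 hardly differed (-0.02, adjusted p = 0.934).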
